A study of Brassica napus with 6 samples.

How the data were processed

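Leaves of 3 euploid and 3 nullisomic Brassica napus plants or pools, 30 days after planting, were frozen, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. HISAT2 is named as a tool in the submitters' processing notes. Its version, the program that computed expression, the genome build and the annotation are not given in the sources used here. The deposited table holds FPKM per gene and library with 2 decimals, computed by the authors, with no counts. It also holds the authors' group means in FPKM, which differed from the means of the 3 libraries by at most 3.33e-05 FPKM and were not used further. No column of per-sample values was left unmapped, and columns were tied to samples through the sample descriptions.

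FPKM divides fragments by gene length and by the fragments mapped in the library, so values are relative within a library: the loss of 1 chromosome's transcripts raises the share of all others, and a few abundant genes can lower the rest. The 10 most abundant genes took 8.69% to 10.5% of summed FPKM. Of the listed lengths 85.5% were multiples of 3, and the length is therefore treated as coding length. An exact 0 can be a failed estimate, so such genes are said to be listed at 0 and no fold is given against them. The A and C subgenomes hold near-identical genes that share reads; 378 tested genes had values identical to another gene in all 6 libraries, and values of homoeologues and of tandem copies are uncertain to that extent.

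Chromosomes were read from the gene identifiers, which name 19 chromosomes; 96921 gene models were placed, and scaffold genes and assembled loci with no chromosome were kept apart as unplaced. As a check, 25406 genes were matched by protein accession to the RefSeq gene table of another assembly, Da-Ae; 91.1% lay on the chromosome of the same name, and the gene order correlated with a Spearman rho of at least 0.949 on each chromosome. No coordinates were taken from that table. Gene names and descriptions come from the protein hits listed in the deposited table.

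Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with empirical Bayes moderation using trend and robust options and Benjamini-Hochberg adjustment at 0.05. A log2 change is nullisomic minus euploid on the log2(FPKM + 1) scale, which understates the change of low genes. A gene is said to have risen or fallen where its adjusted p was under 0.05. Shares, sums and totals of single libraries were compared by two-sided exact permutation tests, whose smallest p is 0.1 for 3 against 3. The Mann-Whitney comparison of A01 genes with and without a pair takes its p from permutations, chosen after the rank test itself (p = 0.0684 across genes) had been run. Gene lists, matched by phrases in the product descriptions, and chromosomes were tested with limma camera at a preset correlation of 0.01 on genes outside C01, with an estimated correlation and fry as alternatives; lists needed 5 tested members. Terms of 10 to 500 tested genes were tested by a one-sided hypergeometric test against all tested genes outside C01. Pairs of A01 and C01 genes were formed where both had the same Swiss-Prot hit and each was the only such gene on its chromosome, which gave 1946 pairs whose order on both chromosomes correlated with a rho of 0.994. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Intervals in the closing section are 95% bootstrap intervals over genes from 2000 draws.

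The lists cover photosystem and light-harvesting proteins, the Calvin cycle, chlorophyll synthesis, cytosolic and organelle ribosomal proteins, the proteasome, heat shock proteins and chaperones, pathogenesis-related proteins and chitinases, WRKY factors, NBS-LRR resistance proteins, jasmonate, ethylene response factors, glucosinolate synthesis and breakdown, flavonoids, the circadian clock, flowering time, antioxidant enzymes, auxin response, cell cycle and histones, the cell wall, ABA, cold and drought, transposons, and DNA methylation and small RNA, with markers of seed, flower, root and stele, guard cell, phloem and dividing meristem. Named genes followed a fixed rule: outside C01 the 8 described genes with the largest change in each direction among those with an adjusted p under 0.05, groups that do not overlap and a mean of at least 5 FPKM in the higher group; on C01 the 4 most abundant described genes that fell and the 3 with the highest nullisomic mean; on A01 2 per direction under the first terms; and per list the called member with the largest rise and fall, or 2 of each for lists past the set test, of which the text gives a part.

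The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined: pseudocounts of 0.1 and 0.01, no filter on low values or a mean of at least 5 FPKM, 4 scalings, eBayes without trend, the replicate number as a block, each library left out, a 2-fold limit, other set tests and C01 genes included. An alternative with scaffold genes assigned to chromosomes was not run, since the scaffold identifiers carry no chromosome. Tests were first run on simulated data drawn from the euploid means and fitted depths with an assumed replicate dispersion. The changed genes were drawn from those with a euploid mean of at least 5 FPKM, so recovery of lower genes was not measured. For nullisomic against euploid, in a fit of 47905 genes, limma recovered 32 of 50 genes raised 2-fold and 22 of 50 lowered 2-fold (0.5). It recovered all 50 of 50 genes changed 4-fold in each direction and called 7 of 47655 unchanged genes.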

Results

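Leaf RNA was profiled by sequencing in Brassica napus (oilseed rape), an allotetraploid that carries the A subgenome of Brassica rapa and the C subgenome of Brassica oleracea. The plants were 30 days old. The 3 euploid libraries came from the cultivar Oro, and the 3 aneuploid libraries carry the cultivar label null. The series title describes the aneuploid plants as nullisomic for chromosome C1, that is, lacking the C1 pair. The labels thus do not give both groups the same cultivar, and a difference in background cannot be told apart from the loss of C1. The table gives FPKM (fragments scaled to gene length and to the mapped fragments of the library) for 105952 gene models, and chromosome C1 appears in the gene identifiers as C01. Summed FPKM was 1289650, 1307227 and 1207725 in euploid replicates 1 to 3 and 1347504, 1287177 and 1269290 in nullisomic replicates 1 to 3. Genes at 1 FPKM or more numbered 47314, 46556 and 46436 in the euploid and 41919, 43074 and 44675 in the nullisomic libraries. The table holds no counts. The spacing of the low values was best fitted by 21200000, 18200000 and 17800000 fragments for the euploid and 19300000, 16700000 and 17800000 for the nullisomic libraries. This estimate of depth is rough, since 71.4% to 76.5% of the low values lay within 0.1 of a whole fragment. Nothing in the labels says whether the libraries of a group came from separate plants, so p-values measure the spread between these libraries. This spread may be technical in the euploid group, while the nullisomic libraries differed from each other in whole chromosome blocks, whose values are given with the windows.

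The first question was whether transcripts of C01 were missing from the libraries labelled nullisomic. Genes of C01 made up 3.97% ± 0.151 (SD, n = 3) of summed FPKM in euploid libraries and 1.31% ± 0.0880 (SD, n = 3) in nullisomic libraries, which is 33.0% of the euploid share. The number of C01 genes at 1 FPKM or more was 2232, 2197 and 2196 in euploid replicates 1 to 3 and 863, 912 and 963 in nullisomic replicates 1 to 3. Neither measure overlapped between the groups, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries can give. Of 1271 C01 genes with a euploid mean of at least 5 FPKM, 670 lay below 10% of it in the mean of the nullisomic libraries, and 262 were listed at 0 in all 3. The same limit of 10% was passed by 416 of 22620 genes placed on the other chromosomes.

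Genes of photorespiration and photosynthesis were among the most abundant C01 transcripts that fell. GLDP1 (BnaC01G0055600ZS), the P protein of the mitochondrial glycine decarboxylase, went from 1763 ± 382 to 0.267 ± 0.081 FPKM (SD, n = 3), a log2 change of -10.42 ± 0.18 (SE; limma adjusted p = 1.57e-06). SHM1 (BnaC01G0013200ZS), the serine hydroxymethyltransferase of the same pathway, went from 682 ± 62.9 to 0.227 ± 0.12 FPKM. ATPG (BnaC01G0065300ZS), a subunit of the chloroplast ATP synthase, went from 1357 ± 121 to 8.76 ± 4.62 FPKM, and LHCA3 (BnaC01G0342600ZS), a light-harvesting protein of photosystem I, from 1342 ± 143 to 35.0 ± 19.7 FPKM. In all, 1538 of 2097 tested C01 genes fell and 28 rose (limma, Benjamini-Hochberg adjusted p under 0.05), with a median log2 change of -1.77; 17 rose without euploid replicate 3.

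Other C01 gene models kept high values. The 3 with the highest nullisomic means were PSAE1 (BnaC01G0100600ZS), a photosystem I subunit, at 1084 ± 113 FPKM in euploid and 1033 ± 115 FPKM in nullisomic libraries (SD, n = 3), GDH3 (BnaC01G0308800ZS), an H protein of glycine decarboxylase, at 851 ± 62.7 and 1009 ± 133 FPKM, and GLO2 (BnaC01G0439700ZS), a glycolate oxidase of photorespiration, at 622 ± 59.6 and 890 ± 48.6 FPKM. GLO2 rose by 0.52 ± 0.13 on the log2 scale (SE; limma adjusted p = 0.0278), a call that ended when any 1 of the 6 libraries was left out (adjusted p = 0.0527 to 0.0811). Near-identical copies on A01 can share reads with such genes, and the assignment of their reads to a chromosome is uncertain.

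The loss was not uniform along C01. Tested genes were placed in identifier order and divided into 12 windows of about 175 genes, and each library's median shift from the euploid mean was taken relative to that library's median over genes outside C01. In windows 1 to 9 the relative shift was -1.97 ± 0.07 (log2, SD, n = 3), with 1399 of 1573 genes lower, and genes there with a euploid mean of at least 5 FPKM had a median of 3.84% of their euploid level. Window 10 lay at -1.36 ± 0.05. In windows 11 and 12 together the shift was -0.01 ± 0.09, with 44 of 349 genes lower and 5 higher. The nullisomic libraries parted from each other in these end windows: the shifts in replicates 1, 2 and 3 were -0.10, 0.05 and -0.59 in window 11 and -0.09, 0.11 and 0.45 in window 12. The joint value thus averaged opposite shifts in replicate 3. In replicates 1 and 2 this end of C01 stayed near the euploid level. Transcripts placed there were not lost as they were in windows 1 to 9. The largest shift of any euploid library in any of the 228 windows of the genome was 0.09. Euploid shifts were taken from the mean of the same libraries, which holds them near 0. This value therefore understates the spread to set beside the nullisomic shifts.

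**Figure D1:**
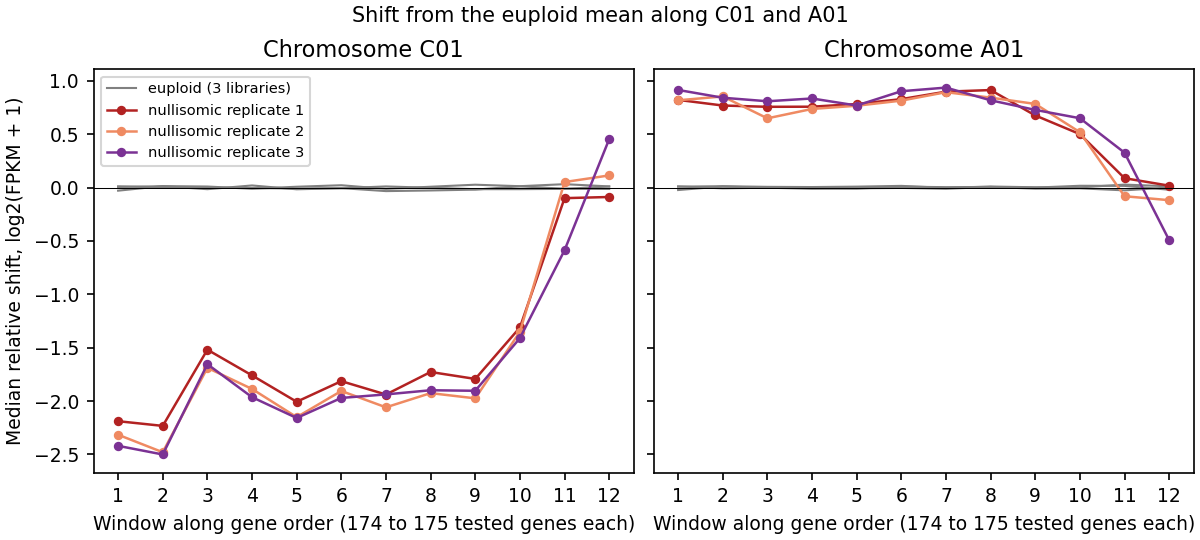
Median shift of log2(FPKM + 1) from the euploid mean (vertical axis), relative to each library's median outside C01, in 12 windows along the gene order of C01 (left) and A01 (right); grey lines are the 3 euploid libraries and coloured lines with points are the 3 nullisomic libraries. C01 lies between -2.50 and -1.31 in windows 1 to 10 and near 0 in window 12 for replicates 1 and 2, while A01 lies between 0.50 and 0.94 in windows 1 to 10.

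A01 is the homoeologue of C01, the counterpart chromosome in the A subgenome, and its genes were higher in the nullisomic libraries along most of its length. The share of A01 in summed FPKM was 3.39% ± 0.0859 in euploid and 6.12% ± 0.370 in nullisomic libraries (SD, n = 3; exact permutation p = 0.1, the smallest possible), or 180% of the euploid share. In windows 1 to 9 the relative shift was 0.82 ± 0.03 (log2, SD, n = 3), with 694 of 1569 genes higher and 30 lower, and genes with a euploid mean of at least 5 FPKM stood at a median of 174% of it. In windows 11 and 12 together the shift was -0.07 ± 0.09, and here too replicate 3 went opposite ways. It lay at 0.33 in window 11, against 0.09 and -0.08 in replicates 1 and 2. In window 12 it lay at -0.49, against 0.02 and -0.12. In each of these windows the A01 shift of replicate 3 had the opposite sign to its C01 shift, and the cause was not tested. Over the whole chromosome 770 of 2091 tested genes rose and 59 fell.

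The median log2 change of A01 genes exceeded that of the other placed chromosomes by 0.70 (limma camera with a preset correlation, Benjamini-Hochberg adjusted p = 7.01e-26 over 18 chromosomes, higher in 3 of 3 nullisomic libraries; adjusted p = 0.479 with an estimated correlation). Chromosome C09 (adjusted p = 0.00151), C02 (0.0436) and A03 (0.0457) were called lower by the same limma camera test, and with an estimated correlation the adjusted p was 0.999 for each. Relative to genes outside C01, the medians in nullisomic replicates 1, 2 and 3 were -0.59, -0.23 and -0.06 for C09, -0.24, 0.03 and -0.13 for C02 and -0.16, -0.07 and -0.14 for A03. C09 was thus lower mainly in replicate 1, and C02 was not lower in replicate 2. The A01 gene with the largest rise under the naming rule was a UPF0725 family gene (BnaA01G0074100ZS), at 0, 0 and 0.06 FPKM in euploid and 75.3, 74.1 and 90.8 FPKM in nullisomic libraries. SMO1-3 (BnaA01G0126300ZS), a sterol methyl oxidase, rose from 1.67 ± 0.498 to 43.0 ± 8.95 FPKM (SD, n = 3). CCT1 (BnaA01G0149800ZS), an enzyme of phosphatidylcholine synthesis, fell from 30.3 ± 5.12 to 0.047 ± 0.045 FPKM, and WRKY18 (BnaA01G0058600ZS), a transcription factor of defence responses, fell from 55.2 ± 19.8 to 2.19 ± 0.53 FPKM.

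Expression summed over both homoeologues was taken from pairs of A01 and C01 genes. In 1370 tested pairs that share 1 protein hit, A01 members supplied 46.9% ± 0.787 of summed pair FPKM in euploid and 84.0% ± 0.661 in nullisomic libraries (SD, n = 3; exact permutation p = 0.1). Summed FPKM of the C01 members went from 33545 ± 853 to 10727 ± 705 and that of the A01 members from 29627 ± 233 to 56288 ± 2511. The pair total was 62443, 63240 and 63834 FPKM in euploid replicates 1 to 3 and 63663, 67854 and 69528 FPKM in nullisomic replicates 1 to 3. The exact permutation p was 0.2, where 0.1 is the smallest possible, so that no difference could pass 0.05. Of 1117 pairs with both members tested, 848 had a C01 member that fell, and in 428 of these the A01 member rose.

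Tested pair by pair with limma, the sum rose in 94 pairs and fell in 216, and its median log2 change was -0.16, against -0.15 for all genes placed outside C01. This balance depended on scaling: with median centring 158 sums rose and 177 fell, and with quantile normalization 170 rose and 135 fell. The median of the sums was -0.08 without nullisomic replicate 1 and -0.24 without nullisomic replicate 3. Of 1252 A01 members tested, 493 rose and 24 fell, and 328 rose without euploid replicate 2. A01 genes with a pair had a median log2 change of 0.56 (1252 genes) and those without one 0.50 (839 genes). A two-sided permutation test of the Mann-Whitney statistic across these genes, which are not independent, gave p = 0.0674 (100000 resamples). Genes without a pair include those with no protein hit and those whose hit was repeated on either chromosome. Such genes can still have a lost C01 counterpart. The count of sums that rose was 41, 35 and 42 without euploid replicate 1, 2 and 3 and 52 without nullisomic replicate 2. The count of sums that fell was 109, 123 and 111 without those euploid replicates and 137 without nullisomic replicate 1.

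**Figure D2:**
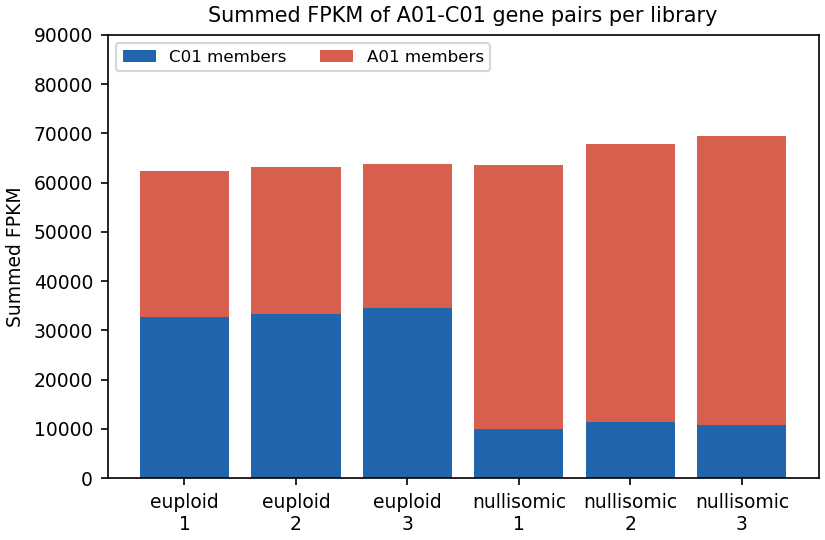
Summed FPKM of 1370 A01-C01 gene pairs (vertical axis, FPKM) in each of the 6 libraries, with the C01 members in blue at the base and the A01 members in red above them. The A01 members supply 46.0% to 47.5% of the sum in euploid and 83.2% to 84.4% in nullisomic libraries.

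Segments of other chromosomes moved as blocks. Window 1 of C02 lay at -1.96 ± 0.23 (relative log2 shift, SD, n = 3) and its window 4 at -0.98 ± 0.08, while window 1 of A02, the homoeologue of C02, lay at 0.69 ± 0.08. Windows 2, 3 and 4 of A03 lay at -0.56 ± 0.18, -0.51 ± 0.14 and -0.44 ± 0.12. In all, 16 of 216 windows outside C01 shifted by at least 0.3 in the same direction in all 3 nullisomic libraries, 10 of them on A01. These shifted windows, chosen after the data were seen, held 830 genes that rose and 584 that fell among 2992 tested, or 47.3%. The remaining placed genes outside C01 held 1871 that rose and 3945 that fell among 37828, or 15.4%. The windows were picked by the shift of these same genes, so a higher share of calls in them is built in.

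**Figure D3:**
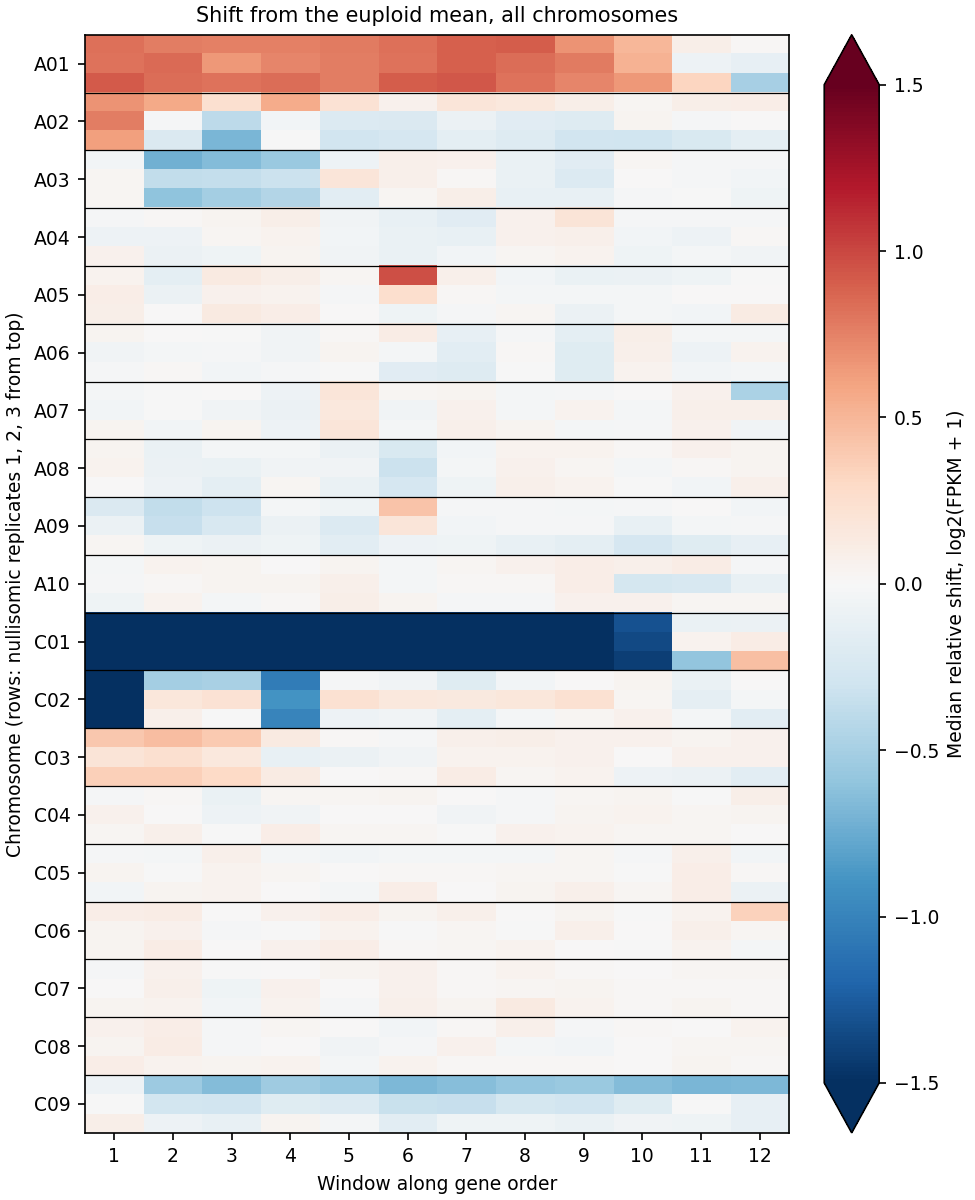
Median shift of log2(FPKM + 1) from the euploid mean, relative to each library's median outside C01, as colour (red higher, blue lower, with values beyond 1.5 drawn at the end colours), in 12 windows along the gene order of 19 chromosomes. Each chromosome has 3 strips for nullisomic replicates 1, 2 and 3 from top to bottom; the blocks named in the text appear on C01, A01, C02, A02 and A03, and C09 is lower mainly in replicate 1, at -0.59 over the chromosome against -0.23 and -0.06 in replicates 2 and 3.

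Outside C01, gene expression differed widely between the groups. Their cultivar labels differ, so background and the loss of C1 cannot be told apart as sources of these differences. Libraries correlated at 0.953 within the euploid group (Pearson r across genes, which are not independent replicates), at 0.926 to 0.937 within the nullisomic group and at 0.791 to 0.807 between groups. Of 40820 tested genes placed on other chromosomes 2701 rose and 4529 fell, and of 4738 unplaced genes 639 rose and 895 fell (limma, Benjamini-Hochberg adjusted p under 0.05). At least 4-fold changes were found for 495 placed genes that rose and 745 that fell. Over all 47655 genes tested, C01 included, 3368 rose and 6962 fell, and the groups did not overlap for 38.9% of genes against 10% by chance. Of these, 12704 lay lower and 5841 higher in nullisomic libraries. The rate by chance allows for no offset shared by the genes of a library, and no value with centred libraries was taken.

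The balance of rises and falls depended on scaling. The median gene outside C01 lay at -0.15 on the log2 scale, and rises made up 37.4% of the calls there. The 3 nullisomic libraries lay at -0.27, -0.13 and -0.03 from the euploid mean, and without nullisomic replicate 1 the median was -0.08. With libraries centred on their median outside C01 that median was 0.01 and rises were 53.0% of calls (3776 against 3348), and with quantile normalization rises were 59.9% (4340 against 2909). Falls outside C01 numbered 2626, 3009 and 2939 without euploid replicate 1, 2 and 3.

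The largest rises outside C01 started from values at or near 0 in the euploid libraries. SDHAF1A (BnaA04G0253900ZS), an assembly factor of mitochondrial complex II, rose from 3.82 ± 2.18 to 3554 ± 435 FPKM (SD, n = 3), a log2 change of 9.61 ± 0.30 (SE; limma adjusted p = 3.91e-06). A universal stress protein gene, PHOS34 (BnaC04G0002700ZS), was listed at 0 in all euploid libraries and at 132, 133 and 164 FPKM in the nullisomic ones. It has near neighbours in identifier order in COL13 (BnaC04G0001500ZS), PMEI6 (BnaC04G0003100ZS) and RPL7AA (BnaC04G0003500ZS). These were also listed at 0 in all euploid libraries and rose, and whether the rises are separate was not tested. A cyclophilin gene (BnaC09G0111300ZS) was likewise listed at 0 and then at 140, 142 and 133 FPKM, and a subunit of the mitochondrial cytochrome b-c1 complex (BnaA10G0275200ZS) at 0 and then at 112, 128 and 104 FPKM. A metallothionein gene (BnaA05G0400200ZS) had 0, 0 and 5.26 FPKM in euploid and 117, 431 and 290 FPKM in nullisomic libraries. APR2 (BnaA03G0586600ZS), an adenylylsulfate reductase of sulfate assimilation, rose from 2.22 ± 0.531 to 224 ± 43.4 FPKM, and ndhT (BnaA09G0262100ZS), a subunit of the chloroplast NDH complex, from 2.18 ± 0.367 to 212 ± 28.1 FPKM.

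Among the largest falls, the photosystem I gene PSAK (BnaA09G0409900ZS) had 894, 1023 and 708 FPKM in euploid libraries and was listed at 0 in all nullisomic ones. FD2 (BnaA03G0578600ZS), a leaf ferredoxin, fell from 379 ± 55.0 to 0.26 ± 0.255 FPKM (SD, n = 3), a log2 change of -8.25 ± 0.20 (SE; limma adjusted p = 2.17e-06). PCR2 (BnaA09G0630000ZS), a cadmium resistance protein, fell from 408 ± 135 to 0.687 ± 0.361 FPKM. The ribosomal protein gene RPS21C (BnaA06G0348200ZS) had 224, 165 and 169 FPKM in euploid libraries, and the profilin gene PRO5 (BnaA03G0115400ZS), which lies in a shifted window, had 42.6, 57.5 and 46.9 FPKM. Both were listed at 0 in each nullisomic library. Another 3 lay in the shifted windows of C02: RPP3B (BnaC02G0146500ZS), an acidic ribosomal protein, fell from 140 ± 26.9 to 0.203 ± 0.352 FPKM, a chloroplast translation factor (BnaC02G0033100ZS) from 64.9 ± 7.81 to 0.01 ± 0.017 FPKM, and PDX13 (BnaC02G0002200ZS), an enzyme of vitamin B6 synthesis, from 164 ± 5.73 to 2.67 ± 1.12 FPKM.

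Of 30 gene lists, 7 passed the set test on genes outside C01 (limma camera with a preset correlation, Benjamini-Hochberg over lists), 5 of them higher and 2 lower relative to the other genes. Of the 10 splits of the 6 libraries 3 against 3, 8 gave at least 7 lists, the real one included, and the highest gave 11. The other splits mix libraries of both groups and keep part of their difference, so this is not a rate by chance. With an estimated correlation the adjusted p was 0.852 for the antioxidant list and 0.992 for each of the others, and 1 list had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, no list passed (lowest adjusted p = 0.0588, 10 lists at an unadjusted p under 0.05). All list results below are therefore calls under the preset correlation, with direction relative to other genes outside C01. Counts of members that rose or fell depended on scaling, as they did over all genes, and are given also with libraries centred on their median outside C01 and with quantile normalization where the share of rises moved by more than 10 percentage points.

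Calvin cycle enzymes rose for 14 of 73 tested members and fell for 0, or 11 and 0 adjusted over the list alone (limma camera adjusted p = 7.31e-07; adjusted p = 0.992 with an estimated correlation), and under quantile normalization, with 8 rises and 2 falls, the list no longer passed (adjusted p = 0.137). Rubisco activase (RCA, MSTRG.10771), which reactivates the carbon-fixing enzyme, rose from 9.48 ± 0.619 to 1751 ± 169 FPKM (SD, n = 3) at an assembled locus, and a sedoheptulose-1,7-bisphosphatase gene (BnaC06G0196400ZS) from 2.44 ± 0.462 to 11.6 ± 0.875 FPKM. Chlorophyll synthesis rose for 8 of 41 members and fell for 2, or 10 and 3 adjusted over the list alone (limma camera adjusted p = 0.0125; adjusted p = 0.992 with an estimated correlation). Outside the shifted windows its call was lost (adjusted p = 0.251), as it was without nullisomic replicate 1 (0.0971), under quantile normalization (0.137) and with no filter on low values (0.0519). With libraries rescaled to the same sum outside C01 it rose for 6 and fell for 3. With C01 genes included its median log2 change was -0.04 (adjusted p = 0.588), against 0.18 in the main fit and 0.21 under quantile normalization. CHLG (BnaA02G0278600ZS), chlorophyll synthase, rose from 0.143 ± 0.145 to 12.7 ± 2.1 FPKM, HEMA1 (BnaA01G0265800ZS), glutamyl-tRNA reductase on A01, rose from 30.5 ± 1.04 to 78.5 ± 19.2 FPKM, and PORB (BnaC07G0476300ZS), a protochlorophyllide reductase, fell from 14.9 ± 2.12 to 5.36 ± 0.823 FPKM.

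The photosystem and light-harvesting list rose for 19 of 177 members and fell for 13, or 19 and 11 adjusted over the list alone (limma camera adjusted p = 0.041, higher; adjusted p = 0.992 with an estimated correlation), and under quantile normalization it was called lower (adjusted p = 0.0234; 18 rises and 21 falls). Its median log2 change was 0.02 and its mean -0.04, and the median was -0.01 with libraries rescaled to the same sum and -0.05 with the same sum outside C01. Without nullisomic replicate 1 the median was -0.06, and without euploid replicate 2 it was 0.09. The call held under none of the 4 scalings (adjusted p = 0.0557 and 0.0933 for these sums, and 0.0646 with median centring). It was lost with no filter (0.0903), a mean of at least 5 FPKM (0.10) or C01 genes included (0.053). It was also lost without euploid replicate 1 (adjusted p = 0.185), euploid replicate 3 (0.192) or nullisomic replicate 1 (0.978). LHCB3 (BnaC02G0169300ZS), an antenna protein of photosystem II, rose from 13.1 ± 3.01 to 186 ± 76.0 FPKM (SD, n = 3), and a PSAK gene on A08 (BnaA08G0204300ZS) from 389 ± 48.5 to 2167 ± 462 FPKM, beside the A09 copy listed at 0. An LHCA3 gene on A03 (BnaA03G0582000ZS) fell from 28.8 ± 3.81 to 0.1 ± 0.061 FPKM.

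Cytosolic ribosomal proteins rose for 16 of 785 members and fell for 82, or 14 and 55 adjusted over the list alone (limma camera adjusted p = 0.00865, lower; adjusted p = 0.992 with an estimated correlation). The call was lost without euploid replicate 1 (adjusted p = 0.116) or nullisomic replicate 2 (0.50). RPL7AA (BnaC04G0003500ZS), the near neighbour of PHOS34 on C04, was listed at 0 in euploid and at 16.1, 13.7 and 33.0 FPKM in nullisomic libraries. RPL35AA (BnaA02G0210800ZS) rose from 1.31 ± 1.18 to 39.0 ± 12.4 FPKM (SD, n = 3). Organelle ribosomal proteins rose for 17 of 276 and fell for 35 (17 and 34 adjusted over the list alone) without passing the set test (limma camera adjusted p = 0.139). This list passed as lower with a mean of at least 5 FPKM (adjusted p = 0.0211), with quantile normalization (0.00204) and without nullisomic replicate 1 (0.0112). There PSRP6 (BnaC03G0086300ZS) rose from 13.7 ± 2.28 to 91.3 ± 20.5 FPKM and RPL24 (BnaC02G0165500ZS), in a shifted window, fell from 114 ± 21.3 to 2.92 ± 0.793 FPKM. Proteasome subunits rose for 14 of 180 and fell for 10 (12 and 5 alone; adjusted p = 0.508 with limma camera), and heat shock proteins and chaperones rose for 8 of 155 and fell for 24 (8 and 24 alone; adjusted p = 0.962). With median centring and with quantile normalization, organelle ribosomal proteins rose for 20 and 23 and fell for 26 and 28, proteasome subunits rose for 20 and 23 and fell for 8 and 6, and heat shock proteins rose for 18 and 19 and fell for as many.

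Antioxidant enzymes rose for 35 of 197 members and fell for 16, or 37 and 17 adjusted over the list alone (limma camera adjusted p = 0.00109, higher; adjusted p = 0.852 with an estimated correlation), and under quantile normalization the list no longer passed (adjusted p = 0.137). Its largest changes in both directions were glutathione S-transferase T3 genes: BnaC06G0137900ZS rose from 0.077 ± 0.067 to 15.4 ± 1.88 FPKM (SD, n = 3), MSTRG.22336 was listed at 0 in euploid and at 4.88, 62.2 and 10.6 FPKM in nullisomic libraries, and MSTRG.28966 had 10.2, 8.44 and 17.9 FPKM in euploid libraries and was listed at 0 in the nullisomic ones. SODCP (BnaA04G0182200ZS), a chloroplast superoxide dismutase, fell from 47.1 ± 22.6 to 12.2 ± 2.33 FPKM.

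Jasmonate genes rose for 8 of 69 members and fell for 4, or 7 and 3 adjusted over the list alone (limma camera adjusted p = 0.00242, higher; adjusted p = 0.992 with an estimated correlation). With median centring 11 rose and 3 fell, and with quantile normalization 13 and 3. TIFY proteins, known as repressors of jasmonate responses, were at both ends: TIFY10B on A02 (BnaA02G0213500ZS) was listed at 0 in euploid and at 6.01, 7.03 and 8.07 FPKM in nullisomic libraries, TIFY11A (BnaA09G0618000ZS) rose from 1.0 ± 0.61 to 8.26 ± 2.44 FPKM (SD, n = 3), and TIFY10B on C02 (BnaC02G0285000ZS) fell from 11.8 ± 0.679 to 4.95 ± 1.13 FPKM. LOX2 (BnaC06G0315600ZS), a lipoxygenase of jasmonate synthesis, fell from 5.71 ± 0.928 to 1.2 ± 0.476 FPKM.

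Flavonoid and anthocyanin genes fell for 7 of 42 members and rose for 0, or 4 and 0 adjusted over the list alone (limma camera adjusted p = 0.041, lower; adjusted p = 0.992 with an estimated correlation). With median centring and also with quantile normalization 5 fell and 1 rose. The call was lost without euploid replicate 3 (adjusted p = 0.192), nullisomic replicate 1 (0.091) or nullisomic replicate 3 (0.123). It was also lost with libraries rescaled to the same sum (0.0506) or the same sum outside C01 (0.0538), and with C01 genes included (0.0915). With no filter on low values it was lost too (0.223), at a median log2 change of -0.36. That median was -0.65 in the main fit, and -0.69 and -0.73 with these rescaled sums, in that order. CYP75B1 (BnaA10G0256900ZS), flavonoid 3'-hydroxylase, fell from 86.7 ± 45.5 to 19.7 ± 1.81 FPKM (SD, n = 3), and an anthocyanin xylosyltransferase gene (BnaC04G0462200ZS) from 9.22 ± 4.96 to 1.51 ± 1.14 FPKM. The xylosyltransferase call (limma adjusted p = 0.0368) ended without euploid replicate 2 (0.115) or 3 (0.113) and without nullisomic replicate 1 (0.092) or 2 (0.0891).

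The other defence and hormone lists did not pass the set test with the settings fixed for it, and 2 of them passed under others. WRKY transcription factors fell for 28 of 116 members and rose for 3 (29 and 6 adjusted over the list alone, limma camera adjusted p = 0.0642). The list passed as lower with a mean of at least 5 FPKM (adjusted p = 0.00854), without euploid replicate 3 (0.0441) and with the replicate block (0.0477). NBS-LRR resistance proteins rose for 20 of 163 and fell for 31 (20 and 34 alone; 0.508). Pathogenesis-related proteins and chitinases rose for 3 of 70 and fell for 8 (2 and 4 alone; 0.0618), although their median log2 change was 0.25 and the direction of the set test was higher. That median was 0.39, 0.15 and 0.15 without euploid replicate 1, 2 and 3, and 0.12, 0.35 and 0.16 without nullisomic replicate 1, 2 and 3. They passed as higher with no filter on low values (adjusted p = 0.0255), with the same sum outside C01 (0.0452) and with the replicate block (0.0118). They also passed without euploid replicate 1 (0.00981) and without nullisomic replicate 2 (0.00533). A pathogenesis-related gene on A01 (BnaA01G0129700ZS) rose from 58.6 ± 17.5 to 999 ± 523 FPKM (SD, n = 3) while the endochitinase CH25 (BnaA03G0328300ZS) fell from 68.1 ± 18.5 to 4.02 ± 4.87 FPKM. Ethylene response factors rose for 6 of 170 and fell for 23 (6 and 23 alone; 0.616), auxin response genes rose for 6 of 211 and fell for 21 (3 and 10 alone; 0.962), and genes of ABA, cold and drought responses fell for 7 of 46 and rose for 0 (7 and 0 alone; 0.876). The excess of falls in these lists shrank or turned with median centring and with quantile normalization. Under these scalings, in that order, WRKY factors rose for 7 and 8 and fell for 17 and 16, resistance proteins rose for 23 and 28 and fell for 24 and 21, and pathogenesis-related proteins rose for 4 and 6 and fell for 3 and 4. Likewise ethylene response factors rose for 13 and 17 and fell for 19 and 15, auxin response genes rose for 12 and 16 and fell for 15 and 13, and genes of ABA, cold and drought responses rose for 4 and 3 and fell for 5 and 7.

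Glucosinolates are defence compounds of the cabbage family. Their synthesis genes rose for 6 of 45 members and fell for 3 (6 and 3 adjusted over the list alone; limma camera adjusted p = 0.0533), and their breakdown genes rose for 3 of 43 and fell for 6 (3 and 9 alone; adjusted p = 0.11). Synthesis genes passed as higher with the same sum outside C01 (adjusted p = 0.0469), with the replicate block (0.0372) and without euploid replicate 2 (0.00379) or nullisomic replicate 2 (0.0222). Breakdown genes passed as lower with a mean of at least 5 FPKM (adjusted p = 0.0424), with quantile normalization (0.00816) and with the replicate block (0.0356). They also passed without euploid replicate 1 (0.00981) or nullisomic replicate 2 (0.00853). With median centring and with quantile normalization, synthesis genes rose for 7 and 9 and fell for 2 and 2. With the same sum outside C01 breakdown genes rose for 2 and fell for 9. AOP2 (MSTRG.51637), a glucosinolate side-chain enzyme, was listed at 0 in euploid and at 6.15, 15.8 and 27.7 FPKM in nullisomic libraries. CYP83A1 (BnaA04G0267400ZS), of aliphatic glucosinolate synthesis, fell from 29.7 ± 13.1 to 6.25 ± 2.85 FPKM (SD, n = 3), and a myrosinase locus (MSTRG.21491), coding for an enzyme that cleaves glucosinolates, fell from 178 ± 77.6 to 3.95 ± 4.12 FPKM.

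Growth and regulatory lists did not pass the set test. Cell wall genes rose for 20 of 337 members and fell for 66 (22 and 73 adjusted over the list alone; limma camera adjusted p = 0.238), and CESA3 (BnaC02G0019500ZS), a cellulose synthase in the first window of C02, fell from 36.9 ± 3.48 to 0.483 ± 0.11 FPKM (SD, n = 3). Cell cycle and histone genes rose for 24 of 319 and fell for 38 (22 and 38 alone; 0.979). Circadian clock genes rose for 4 of 34 and fell for 4 (4 and 4 alone; 0.508), and APRR7 (BnaC02G0007000ZS), a clock repressor also in the first window of C02, fell from 18.2 ± 3.07 to 1.75 ± 0.516 FPKM. Flowering time genes rose for 8 of 76 and fell for 8 (8 and 8 alone; 0.294). Transposon-related genes rose for 16 of 106 and fell for 25 (16 and 26 alone; 0.837), and genes of DNA methylation and small RNA rose for 3 of 52 and fell for 9 (3 and 9 alone; 0.382), with AGO2 (BnaC06G0124700ZS), an argonaute, listed at 0 in euploid and at 7.47, 10.3 and 11.2 FPKM in nullisomic libraries. With median centring and with quantile normalization, cell wall genes rose for 26 and 35 and fell for 43 and 35, and cell cycle and histone genes rose for 30 and 34 and fell for 30 and 29. Clock genes rose for 7 and 8 and fell for 3 and 3 under these scalings, flowering time genes rose for 10 and 12 and fell for 7 and 6, transposon-related genes rose for 17 and 20 and fell for 20 and 15, and genes of DNA methylation and small RNA rose for 4 and 4 and fell for 8 and 6.

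Markers of other organs and cell types did not pass the set test (limma camera adjusted p = 0.139 to 0.962). Seed markers rose for 1 of 7 members and fell for 2 (1 and 2 adjusted over the list alone), and the member that rose was a sinapine esterase gene (BnaA08G0211800ZS), which entered by its name only. Flower markers rose for 8 of 60 and fell for 12 (8 and 12 alone), root and stele markers for 4 of 24 and 2 (4 and 2 alone), guard cell markers for 2 of 19 and 2 (2 and 2 alone), phloem and vasculature markers for 4 of 32 and 0 (2 and 0 alone), and dividing meristem markers for 2 of 38 and 6 (3 and 8 alone). With median centring and with quantile normalization, flower markers rose for 9 and 9 and fell for 8 and 7, root and stele markers rose for 4 and 6 and fell for 1 and 1, and guard cell markers rose for 2 and 3 and fell for 1 and 1. Meristem markers rose for 3 and fell for 5 under each of these scalings, and seed markers rose for 1 and fell for 1. With the same sum outside C01, guard cell markers rose for 1 and fell for 2, and phloem and vasculature markers rose for 3 and fell for 1.

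**Figure D4:**
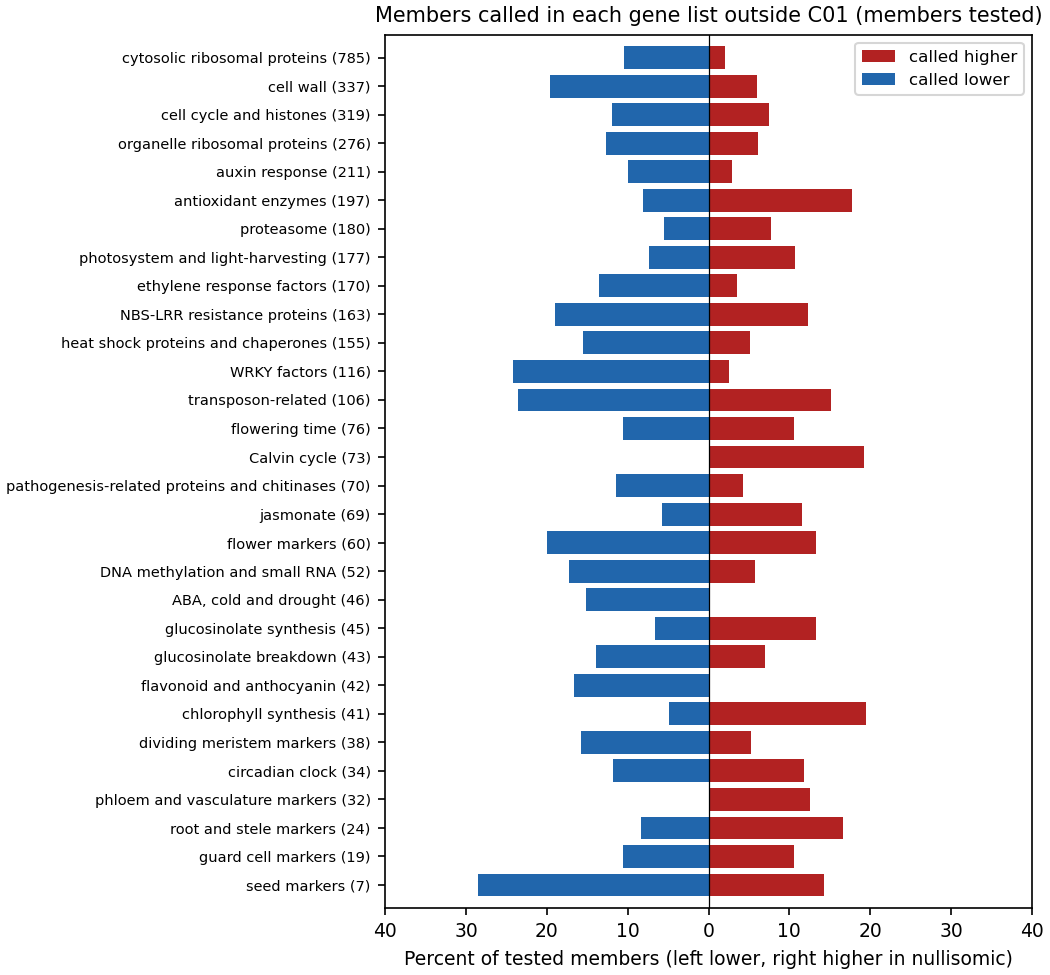
Percent of tested members of each gene list outside C01 that were called higher (red, to the right) or lower (blue, to the left) in the nullisomic libraries, with the number of members tested in brackets and FPKM as deposited, without the scalings that shift the balance of many lists. Calvin cycle members are called higher for 14 of 73 and lower for 0, and cytosolic ribosomal proteins lower for 82 of 785 and higher for 16.

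Among genes outside C01 that fell at least 2-fold, 10 of 2204 annotation terms were enriched (one-sided hypergeometric test, Benjamini-Hochberg). The extracellular matrix term held 11 genes that fell of 24 tested, with 1.78 by chance (adjusted p = 4.49e-04), and plant-type cell wall held 47 of 292, with 21.6 by chance (adjusted p = 4.49e-04). Regulation of systemic acquired resistance, a form of induced immunity, held 8 of 15 (adjusted p = 0.00262), terpene synthase activity 9 of 23 (0.0114), cysteine-type peptidase activity 23 of 126 (0.0177) and ADP binding, the nucleotide-binding function of many resistance proteins, 37 of 262 (0.0291). Among genes that rose at least 2-fold, 0 terms passed the adjusted threshold, with 50 at an unadjusted p under 0.05. With C01 genes included 5 terms were enriched among falls, and with no fold limit 5 were enriched among rises. Terms were tested only on FPKM as deposited, with all 6 libraries and with genes of the shifted windows kept in. Since the balance of rises and falls depended on scaling, whether these terms hold under other scalings was not tested.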

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

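Counts outside the shifted windows were chosen after the data were seen, as was the rule that a fit without 1 library keeps the genes tested with all 6; when the filter was applied anew to 5 libraries, genes expressed in 2 remaining euploid libraries alone dropped out and without a euploid library C01 falls numbered 381 to 406 and falls outside C01 1162 to 1405. Rises then numbered 15 to 20 on C01 and 1573 to 1623 outside it, and without a nullisomic library 9 to 13 and 1442 to 1925. Among named genes, 1331 of 1380 combinations of gene and alternative kept direction and side of the threshold, 49 lost the call (31 with a library left out, 9 genes) and 0 reversed. Most of these genes were picked for the largest changes among called genes, so this stability does not carry over to other calls. The A01 difference ranged from 0.40 (no filter) to 0.86 (pseudocount 0.01). It passed limma camera with the preset correlation under each alternative, but not with an estimated correlation (0.70, adjusted p = 0.479). The planned fry test called A01 genes higher (fry adjusted p = 0.0292), but it does not compare them with other genes and so does not test this difference. Rough depth limits low genes: values under 1 FPKM rest on few fragments.

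With a mean of at least 5 FPKM, which tests fewer genes, 1853 genes rose and 3000 fell, 13 and 631 on C01 and 1621 and 2068 outside, and 137 pair sums fell. Quantile normalization gave 5165 rises in all, 4340 rises and 2909 falls outside C01, and 170 pair sums up and 135 down; median centring gave 158 pair sums up. For these the cause was not tested. A 2-fold limit, which removes smaller changes, left 2182 rises in all and 1602 rises and 2617 falls outside C01. Lists past the set test numbered 0 with an estimated correlation, 0 with fry and 4 with C01 genes included. Enriched terms numbered 5 among rises with no fold limit and 5 among falls with C01 included. The photosystem list turned lower with quantile normalization (median -0.0831, adjusted p = 0.0234) and with fry, which does not compare with other genes (median 0.0242, adjusted p = 0.776).

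Without 1 library, rises on C01 ranged from 17 to 25 (17 without euploid replicate 3). Falls outside C01 ranged from 2626 to 4924 (2626, 3009 and 2939 without euploid replicates 1, 2 and 3). Pair sums up ranged from 35 to 80 (41, 35 and 42 without those, 52 without nullisomic replicate 2). Pair sums down ranged from 109 to 282 (109, 123 and 111 without those euploid replicates, 137 without nullisomic replicate 1). A01 members up ranged from 328 to 479 (328 without euploid replicate 2). Not all counts shrank. Without nullisomic replicate 3, 4924 genes outside C01 and 282 pair sums fell, against 4529 and 216 with all 6 libraries. The cause of these moves was not tested.

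Replicate numbers did not pair the libraries: same-number deviations correlated at 0.05, 0.03 and -0.03, and nullisomic replicate 2 matched euploid replicate 3 best (0.07). With the replicate block 2887 genes rose and 5835 fell, and 11 lists passed.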

Other observations

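The tests of the A02 partners and of C09, the counts of splits and the count of genes with the same protein hit were chosen only after the results they bear on were seen, and so were the limits used for the slope of A01 on its partners. With no fold limit, genes that rose outside C01 were enriched for thylakoid (47 of 323 genes, 23.7 by chance, adjusted p = 0.00615, hypergeometric test), the membranes of photosynthesis, and for water channel activity (10 of 31 genes, 2.27 by chance, adjusted p = 0.0206). Terms among falls also included positive regulation of transcription factor activity (7 of 14 genes), anchored membrane components (26 of 156), enzyme inhibitors (20 of 108) and UDP-glucose 6-dehydrogenase (6 of 13), an enzyme that supplies cell wall precursors. All these terms were tested on FPKM as deposited only.

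Blocks of A03 and C03 moved in opposite directions. Windows 1, 2 and 3 of C03 lay at 0.32 ± 0.11, 0.36 ± 0.11 and 0.29 ± 0.12 (relative log2 shift, SD, n = 3), short of 0.3 in replicate 2, beside the lower windows 2 to 4 of A03. Some blocks differed between the nullisomic libraries: in replicates 1, 2 and 3, window 6 of A05 lay at 0.97, 0.25 and -0.06, window 2 of A02 at 0.57, -0.02 and -0.22, and window 3 of A02 at 0.24, -0.40 and -0.68. The fall of PSAK on A09 beside the rise of PSAK on A08 was followed by a count of similar cases. Of 324 placed genes outside C01 and the shifted windows that fell at least 4-fold, had a euploid mean of at least 5 FPKM and carried a protein hit, 17 had another gene with the same protein hit that rose at least 4-fold, against a median of 11 in 10000 draws of genes matched on the number of genes per hit (share of draws as high 0.0744), so the count was not separated from random draws.

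A01 genes were higher along windows 1 to 9. Reads passing from C01 to shared A01 sequence could act in nullisomic libraries only where C01 transcripts were still present. For 54 A01 genes with no C01 gene of the same hit or one below 0.5 FPKM in euploid libraries, the median shift was 0.71 (95% interval 0.41 to 0.99). This argues against such reads for these genes only so far as hits find the counterparts. A C01 counterpart with another hit, or one on a scaffold, was counted as absent. The slope of the A01 shift on the lost partner was 0.37 (0.187 to 0.52, 531 pairs). Simulated data on 718 pairs gave 0.90 for a proportional rise and -0.005 for a constant rise. Beyond that rise, the simulation held no differences of single genes between the groups. The euploid A01 level enters both the predictor and the shift, so such differences alone can give a slope above 0. A rise in proportion to the partner predicted a slope of at least 0.70. The upper limit of the observed slope was 0.56 after correction for noise in the predictor, below that prediction. That limit was chosen afterwards, and the slope of at most 0.3 set beforehand was not met. The correction covers noise between libraries only. Wrong pairs and reads shared between the copies can also lower the slope, and the simulation held neither. The slope therefore cannot decide on a proportional rise as the whole cause. The lower limit above 0, also chosen afterwards, cannot decide on a rise with no dependence on the partner, for the reason given. A full or partial dependence on the partner stays open. So does a rise of the whole region that extra copies of A01 may give, beside it or alone. Genes with a strong partner exceeded those with none or one below 0.5 FPKM by 0.23 (-0.06 to 0.54).

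The first window of C02 was lower and the start of A02 higher. Failure of a diverged C02 haplotype to map would leave A02 unmoved and is argued against, as the whole cause, by part of the pattern itself: the A02 partners of those genes shifted by 0.81 (95% interval 0.72 to 0.91, 93 genes). A candidate explanation is replacement of the C02 segment by its A02 counterpart, which predicts a steady pair sum: the sums shifted by -0.12 (-0.24 to -0.02, 101 pairs). Reads passing from C02 to A02 copies predict a steady sum too and cannot be told apart from replacement. Only 4 genes in window 1 of A02 had no C02 gene of the same hit or one below 0.5 FPKM. Replacement would raise these genes, but their median shift was -1.75, and 4 genes are too few to decide. No DNA was analysed here, and differences in background between the groups other than C1 stay untested.

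C09 was lower in nullisomic replicate 1, at -0.59 over the chromosome. A fall of all C chromosomes in that library is argued against by a lowest median of -0.00391 among C03 to C08. Whether that library had 1 copy of C09 fewer cannot be told apart: genes of at least 20 FPKM shifted by -0.69 (-0.76 to -0.64, 416 genes), at the edge of the range set for it, and by -0.24 and -0.11 in replicates 2 and 3.

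The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, gave as many called genes (10330; highest other 3), as many on C01 (1566; 0) and outside it (7230; 1), as large an A01 difference (0.70; 0.26) and as many called pairs (310; 0). For the gene lists 8 of the 10 splits gave as many, with 7 in the real split and 11 in the highest other. Each of the other splits mixes libraries of both groups, so the group difference enters its spread and few called genes are built in. Such splits also keep part of the group difference. They therefore give no rate by chance, for genes, pairs or lists, and cannot decide on it.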
